A study of Homo sapiens with 4 samples.

How the data were processed

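RNA abundance was measured in SK-BR-3, an established human breast cancer cell line with HER2 amplification and a missense-mutant p53, on 1 Affymetrix array of 54675 probe sets per culture. Per the labels' protocols, cells were transfected with a p53 shRNA vector or with its control, which the labels call both control shRNA and an empty vector, and were selected with puromycin. The selected cells then received siRNA against Pontin or were left in the arm whose titles read sicon, a term the labels do not spell out. RNA was collected 24 h after siRNA transfection, and 200 ng of total RNA was labelled per array. The 4 groups, each taken from the sample titles, were control shRNA, p53 shRNA, Pontin siRNA with control shRNA, and p53 shRNA with Pontin siRNA, with 1 array each. The labels do not say whether the siRNA arms came from separately selected shRNA populations, and they give no siRNA sequence.

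The deposited values are MAS5 signals on a linear scale, per the submitters' processing notes, which name the tool without a version. In the deposited signal table, the mean of each array without its lowest and highest 2% was 150.0, so each array had been scaled to a common level by the authors. No detection calls, scanner files or array dates were used here. Precision is limited by the number of arrays.

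Probe sets were named through the platform annotation, with symbols updated through Entrez gene identifiers in a table of human genes. Of the probe sets, 41097 carried exactly 1 gene symbol, 1801 carried several and 11777 had none listed. Of those with 1 symbol, 41043 matched the gene table. Probe sets with several symbols or none, and 62 Affymetrix control probe sets, were left out of the gene analysis. The transcript targeted by the p53 shRNA is not reported here, so the depth of the p53 knockdown was not checked and the alternatives listed for it were not run.

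Signals were taken to log2 with no further normalization and no pseudocount. The 14 signals of 0 in the whole table were set to 0.1, the lowest signal above 0, and none of them fell in a gene kept. Each of 19775 genes was represented by its probe set with the highest mean log2 signal over the 4 arrays. The 12066 genes whose mean was at or above the median of all probe sets, a signal of 15.3, were kept. Of these, 7744 genes lay at or above the 75th percentile of all probe sets by mean signal, 110.3. They are called bright genes, and counts are given for them separately.

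With 1 array per group there was no replicate within a group, and differences were judged by size. A fit that takes the 2 pairs as replicates was run only as an alternative. Each knockdown was measured in 2 matched pairs with no array in common. For p53 shRNA these were p53 shRNA over control shRNA, and p53 shRNA with Pontin siRNA over Pontin siRNA. For Pontin siRNA they were Pontin siRNA over control shRNA, and p53 shRNA with Pontin siRNA over p53 shRNA. A gene was called where both log2 ratios had the same sign and were at least 1.5-fold, which is 0.58 in log2. Genes at least 1.5-fold apart in both pairs with opposite signs were counted beside the calls as a gauge of array noise or interaction. The mean p53 ratio, the mean Pontin ratio and the departure from additivity divided by 2 are the contrasts given by the 3 ways of splitting 4 arrays into equal groups, and they carry equal array noise. The departure from additivity was the log2 signal with both knockdowns minus those with each single knockdown plus that of the control.

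Named genes followed a rule fixed before the data were examined. It took RUVBL1 and RUVBL2, the 12 genes called higher and the 12 called lower for each knockdown with the largest smaller-pair ratio, up to 8 genes per direction pattern among genes called for both knockdowns, the 6 highest and 6 lowest departures among genes at least 2-fold apart in a direct comparison, and called members of the gene lists. List members given as examples without a call, and genes said to lie outside the rule, were chosen after their values were seen. The 20 lists, also fixed before, covered wild-type p53 targets, genes reported as raised by mutant p53, Pontin and Reptin complexes, PIKK kinases with the TTT complex, ribosome biogenesis, G1/S and DNA replication, G2/M and mitosis, cholesterol synthesis, proteasome, unfolded protein and integrated stress response, heat shock, type I interferon response, NF-kB targets, hypoxia and glycolysis, HER2 amplicon and luminal epithelium, basal epithelium, mesenchymal and invasion genes, immune cells, replication-dependent histones and housekeeping genes. For each list, the median of its members' mean log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean signal in 10 bins, as a description of these 4 arrays. The random lists were drawn from the genes kept, with the signals as deposited. Medians under alternatives were set against these same ranges, which were not redrawn, so their place relative to the ranges is approximate.

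Noise in simulated arrays was set by signal from the departures from additivity, so any interaction counts as noise there. It was a spread within signal bins that lay below the plain SD of these departures, so simulated noise may be too low for extreme values. The calling rule was tested on simulated data over 12066 genes, with 100 genes changed per knockdown. For 2-fold changes it recovered 100 of 100 bright p53 and 99 of 100 bright Pontin genes, and 74 and 68 of 100 below it. For 3-fold changes it recovered all 100 bright genes for either knockdown and 98 of 100 below it. Alternatives were median centring over the genes kept, quantile and cyclic loess normalization, no filter on signal, bright genes alone, a pseudocount of 4.5 (the 25th percentile of all signals), the mean over probe sets of a gene, leaving out cross-hybridizing probe set types, a 2-fold threshold, and an additive limma fit with 1 residual degree of freedom at an adjusted p of at most 0.05. In a simulation of that fit over 12066 genes with 200 genes changed 4-fold in the p53 arm, 193 were recovered with 13 false p53 calls and 1 false Pontin call. Each array was also left out in turn, an alternative added after the data were examined. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.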

Results

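SK-BR-3 cells carrying control or p53 shRNA, each with or without siRNA against Pontin, were profiled on 4 arrays, 1 per group. Pontin, encoded by RUVBL1, is an AAA+ ATPase of chromatin remodelling and protein assembly complexes, and the design asks which transcripts depend on mutant p53, on Pontin, or on both. The median signal over all probe sets was 15.9 with control shRNA, 16.0 with p53 shRNA, 16.5 with Pontin siRNA and 19.6 with both. Across the 12066 genes kept, log2 signals of any 2 arrays correlated at 0.981 to 0.988. No group had a replicate, so every difference is given in 2 matched pairs and no p-value is attached to any gene.

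RUVBL1, the target of the siRNA, had a signal of 477.7 with control shRNA and 127.4 with Pontin siRNA, 3.75-fold lower. In p53 shRNA cells it was 398.2 without and 65.8 with Pontin siRNA, 6.05-fold lower. These values came from its single named probe set. RUVBL2, which encodes the partner ATPase Reptin, had signals of 2428 and 2771 in the first pair and 2575 and 2723 in the second, log2 ratios of 0.19 and 0.08.

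Genes lower with p53 shRNA included TOX3, an HMG-box nuclear protein gene of luminal breast cells. Values are given first for cells without and then for cells with Pontin siRNA. TOX3 was 11.9-fold and 14.1-fold lower, from 1025.5 to 86.3 and from 864.4 to 61.2. Its 4 probe sets were all of the types left out as cross-hybridizing in an alternative, so TOX3 could not be checked there. The same held for RUVBL1, OLFM4, H2AC6, IGFBP3 and EGLN3, among other genes. The dimmest TOX3 probe set, with signals from 8.4 to 19.6, gave log2 ratios of -1.22 and -0.18. The other TOX3 probe sets were at -3.57 or lower in both pairs. PIP, which encodes prolactin-induced protein, an apocrine secretory product, had log2 ratios of -2.12 and -1.98, and OLFM4, which encodes a secreted glycoprotein, -1.85 and -2.01. The neuroligin gene NLGN4X was at -1.22 and -1.55, and GATA3, a luminal transcription factor, at -0.96 and -0.67.

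Genes higher with p53 shRNA included IGFBP3, an insulin-like growth factor binding protein gene, with log2 ratios of 2.25 and 2.48. MGP, which encodes matrix Gla protein, was 4.01-fold and 3.35-fold higher, and TFPI2, a serine protease inhibitor gene, had log2 ratios of 1.62 and 1.29. The matricellular gene CCN2 was at 1.24 and 1.07, and EGLN3, a hypoxia-induced prolyl hydroxylase gene, at 1.06 and 1.06. HDAC8 was at 1.71 and 1.69 on its brightest probe set. Its probe sets disagreed: the means of the pairs were 1.70, 1.03 and -0.10 on the 3 probe sets of the gene.

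By the 1.5-fold rule, 167 genes were higher and 104 lower with p53 shRNA in both pairs, while 106 genes were that far apart with opposite signs. Among the 7744 bright genes, at or above a mean signal of 110.3, 17 were higher, 32 lower and 0 opposite. Arrays simulated with no change gave 111 calls on average (79 to 141) over all genes kept. The other genes with the largest lower calls were NFATC4, PDZK1IP1, P3H2, GJC1, ZBTB7C, PTPRM, SLC16A10 and BCL11B, and the other largest higher calls were FLJ46875, LOC100287808, LINC02256, FOXP2, AGPS, MIR1-1HG, PSG7 and KLF3-AS1, none of them bright. Higher calls were 61.6% of the calls as deposited, 48.3% after quantile and 49.0% after cyclic loess normalization.

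**Figure D1:**
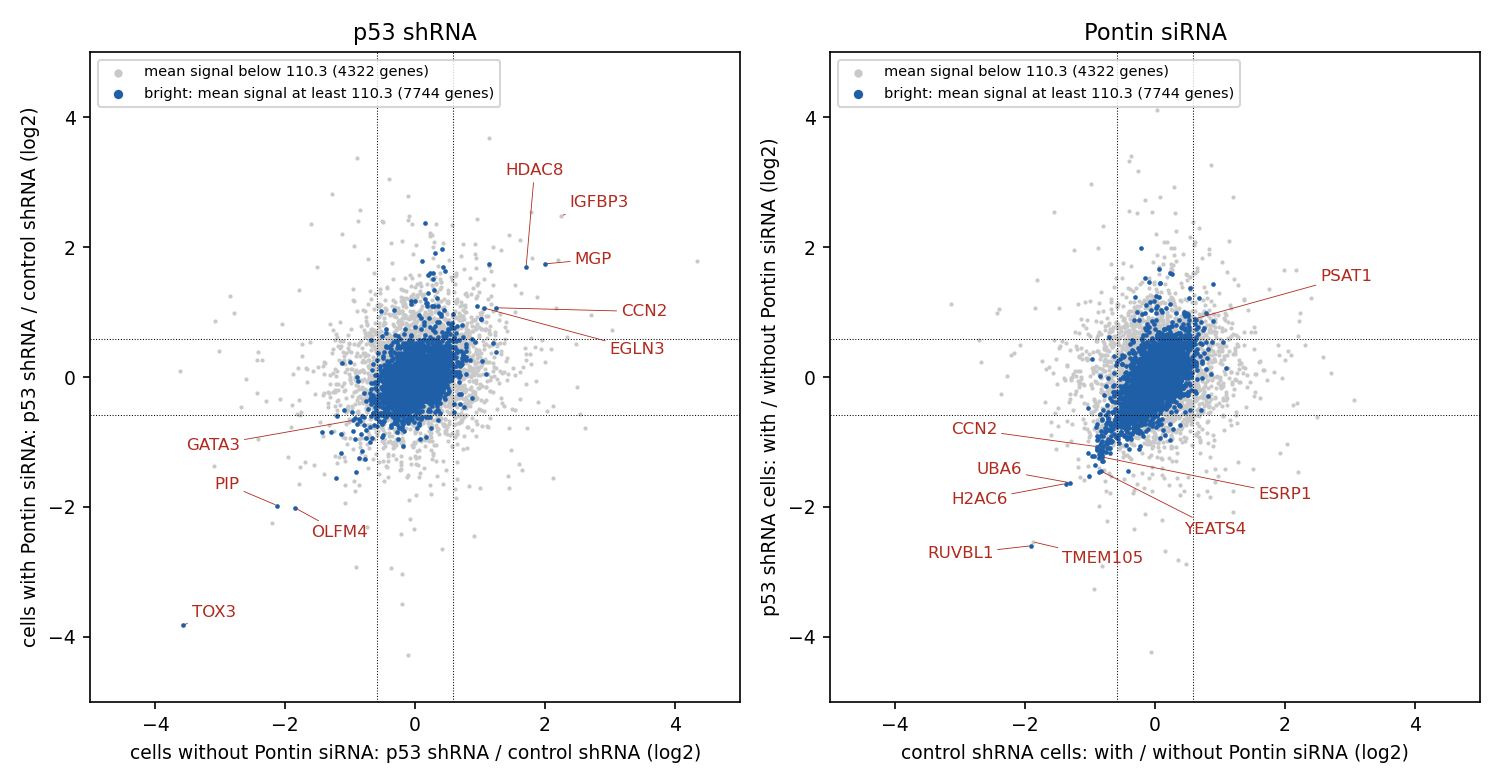
Log2 ratios of 12066 genes in the 2 matched pairs of each knockdown: p53 shRNA over control shRNA without (x) and with (y) Pontin siRNA on the left, and with over without Pontin siRNA in control shRNA (x) and p53 shRNA cells (y) on the right. Each point is a gene, blue if bright, and dotted lines mark 1.5-fold; TOX3 lies at -3.57 and -3.82, and RUVBL1 at -1.91 and -2.60.

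With p53 shRNA the hypoxia and glycolysis list had a median above 0 and the G1/S and DNA replication list a median below 0, with few or no members called. Of 24 hypoxia and glycolysis genes kept, 21 had a mean ratio above 0 and 19 were above 0 in both pairs, with a list median of 0.24 that exceeded all 10000 random lists. EGLN3 alone was called higher. The angiogenic factor gene VEGFA was at 0.57 and 0.83, BNIP3, a mitophagy receptor gene, at 0.52 and 0.57, the aldolase gene ALDOC at 0.49 and 0.53, and SLC2A1, which encodes the glucose transporter GLUT1, at 0.41 and 0.35. PKM, at -0.33 and -0.18, and PFKFB3, at -0.07 and -0.22, lay on the other side. Of 29 G1/S genes kept, 27 had a mean ratio below 0 and 22 were below 0 in both pairs, with a median of -0.17 that lay under all random lists, and 0 were called. E2F1, a transcription factor gene of S-phase entry, was at -0.67 and -0.27, GINS2, which encodes a replicative helicase subunit, at -0.47 and -0.30, the phosphatase gene CDC25A at -0.45 and -0.28, and FEN1, a flap endonuclease gene, at -0.36 and -0.43. The G1/S median kept its sign and lay between -0.17 and -0.16 under all 8 alternatives run on it. The hypoxia median was 0.05 with the mean over probe sets, inside the central 95% of random lists (-0.07 to 0.08), and SLC2A1 was then at 0.04. It was at least 0.20 under the other alternatives. The labels do not say whether the 2 pairs used separately selected cells.

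Ribosome biogenesis genes had a median of -0.09 with p53 shRNA (percentile 0.64 of random lists, 15 of 28 below 0 in both pairs), with UTP4 at -0.29 and -0.36 and NOP14 at -0.51 and -0.33. With the mean over probe sets this median was -0.06, inside the central 95% of random lists. Mitotic genes had a median of -0.06 (percentile 4.77). Among 23 wild-type p53 targets kept, 0 were called and the median was -0.01, with 10 above and 13 below 0. This sign turned under median centring and cyclic loess. Among 19 genes reported as raised by mutant p53, 0 were called, 13 were below 0 and the median was -0.07 (percentile 8.32). It was above 0 with the mean over probe sets. The chemokine gene CXCL1 of that list was at -0.48 and -1.01. The HER2 amplicon and luminal list had a median of 0.07 (percentile 96.2), with GATA3 as its only call.

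Pontin siRNA was accompanied mainly by lower transcripts among bright genes. Values are given first for control shRNA and then for p53 shRNA cells. After RUVBL1, the bright genes with the largest lower calls were H2AC6, a histone H2A gene, at -1.38 and -1.64, UBA6, which encodes a ubiquitin-activating enzyme, at -1.30 and -1.63, and LYRM7, which encodes a respiratory complex III assembly factor, at -1.03 and -1.17. YEATS4, a subunit gene of the SRCAP and TIP60 complexes that also hold Pontin, was at -0.83 and -1.45, and ESRP1, an epithelial splicing factor gene, at -0.81 and -1.23 on its brightest probe set but at -0.17 and 0.04 on its other one. The cytokine gene IL18, with signals from 56.5 to 197.1, was at -1.16 and -1.54.

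With Pontin siRNA, 140 genes were higher and 150 lower in both pairs, and 100 genes were 1.5-fold apart with opposite signs. Among bright genes, 14 were higher, 85 lower and 1 opposite. Arrays simulated with no change gave 110 calls on average (87 to 133) over all genes kept. The other genes with the largest lower calls were TMEM105, LOC101926984, HGD, TOR4A, NAP1L2, DMBT1 and CBLL1-AS1. Another TOR4A probe set, with signals from 13.0 to 19.2, gave only -0.13 and -0.09. The genes with the largest higher calls were LINC01355, CCDC61, LOC100287808, FUT8-AS1, SAMD14, AMT, NPEPL1, ANKRD20A11P, REXO6P, LRRC36, LOC729815 and MAP3K14, and none of their signals exceeded 53.9. Higher calls were 48.3% of the calls as deposited, 28.5% after quantile and 29.1% after cyclic loess normalization.

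With Pontin siRNA the NF-kB list had a median above 0 and the replication-dependent histone list a median below 0. The NF-kB median was 0.24 (percentile 99.7), with 11 of 16 genes above 0 in both pairs and 0 called. NFKBIA, an NF-kB inhibitor gene, was at 0.40 and 0.78, TNFAIP3, a deubiquitinase gene of NF-kB feedback, at 0.40 and 0.65, TNF at 0.50 and 0.46, and the adhesion gene ICAM1 at 0.31 and 0.36, while the chemokine gene CCL2 was at -0.30 and -0.38. Of 10 histone genes, 9 had a mean ratio below 0 and 7 were below 0 in both pairs, with a median of -0.25 (percentile 0.27). H2AC6 was the only call, and the linker histone gene H1-2 was at -0.41 and -0.53. The histone median lay between -0.25 and -0.23 under all 8 alternatives run on it. The NF-kB median was 0.13 without a filter on signal and 0.16 after cyclic loess. Both values lay inside the central 95% of random lists (-0.13 to 0.17), which were not redrawn for these alternatives.

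The 32 genes of Pontin and Reptin complexes had a median of -0.07 with Pontin siRNA (percentile 4.01), with 17 below 0 in both pairs and YEATS4 as the only call. The median was above 0 with the mean over probe sets, at 0.041, but the median of all genes was then 0.037 as well. PIKK kinases and the TTT complex, clients and partners of Pontin-containing chaperones, had a median of -0.06 over 8 genes (percentile 19.7). It was 0.013 with the mean over probe sets, still below the median of all genes. Interferon response genes had a median of -0.15 (percentile 1.49), but the pair medians were near 0 in control shRNA cells and -0.25 in p53 shRNA cells. The median was inside the central 95% of random lists without a filter on signal, with the pseudocount and without cross-hybridizing probe set types, where it was -0.07. G1/S genes had a median of 0.07, just above that range, and were inside it after quantile normalization, among bright genes alone and with the mean over probe sets (0.05). The HER2 amplicon and luminal list had a median of 0.08 (percentile 97.9), with pair medians of 0.01 and 0.07, and its only call, ESRP1, was lower. After quantile normalization this median was 0.04, inside the central 95% of random lists. Wild-type p53 targets had a median of -0.01 (percentile 38.2), a sign that turned among bright genes alone and with the mean over probe sets.

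**Figure D2:**
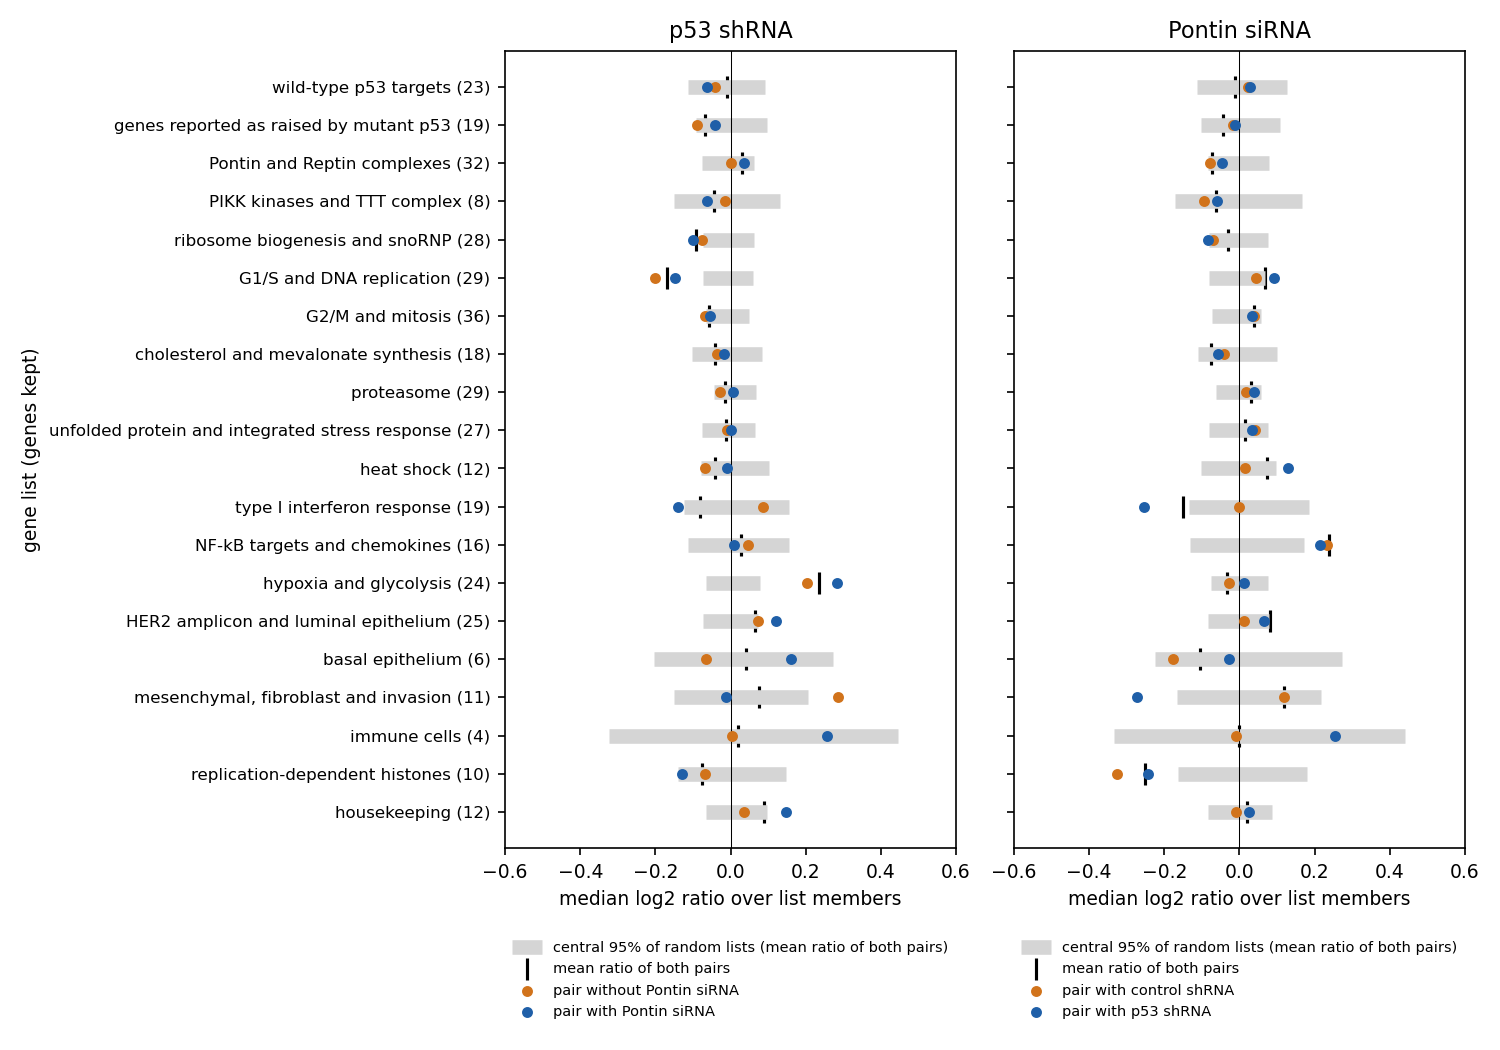
Median log2 ratio over the members of each of 20 gene lists (genes kept in brackets) for p53 shRNA on the left and Pontin siRNA on the right, with a point for each matched pair, a black tick for the mean ratio of both pairs and a grey bar for the central 95% of 10000 matched random lists. With p53 shRNA the hypoxia and glycolysis list lies at 0.24 and the G1/S list at -0.17, and with Pontin siRNA the NF-kB list lies at 0.24 and the histone list at -0.25.

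A question of the design is whether mutant p53 and Pontin act on the same genes. CCN2 was higher with p53 shRNA (1.24 and 1.07) and lower with Pontin siRNA (-0.90 and -1.07), and its signal with both knockdowns, 164.9, was near that of the control, 146.5. The serine synthesis gene PSAT1 was lower with p53 shRNA (-0.92 and -0.64) and higher with Pontin siRNA (0.62 and 0.90), with signals of 709.3 in the control and 699.0 with both. TGFBR3, a TGF-beta co-receptor gene, was lower with p53 shRNA (-0.81 and -0.60) and higher with Pontin siRNA (0.61 and 0.82), with 129.8 and 130.6. Its other probe set gave -0.36 and 0.08 with p53 shRNA and 0.32 and 0.76 with Pontin siRNA, so this gene rests on 1 probe set. These 3 genes were the only bright ones that were called for both knockdowns.

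Over all genes kept, 17 genes were called for both knockdowns in the same direction and 18 in opposite directions, against 3.23 and 3.28 for independent lists of these sizes. Higher with p53 shRNA and lower with Pontin siRNA were 12 genes, among them CCN2, IGFBP3, FLJ46875, ANXA1, CHRND, PCDHB3, RILPL2 and WHAMMP2. The reverse held for 6 genes, PSAT1, TGFBR3, C22orf46P, DLK2, GJC1 and SULT2B1. Higher with both were 16 genes, among them LOC100287808, LINC02256, ELFN1, UNC5B, CYP3A4, KHDC3L, MICAL1 and NEU4, and lower with both was ZBTB42 alone. On another UNC5B probe set, with signals from 48.6 to 64.1, the ratios were -0.22 and 0.37 with p53 shRNA. With Pontin siRNA they were -0.19 and 0.40. A further UNC5B probe set of lower signal was above 0 in each pair. Of these 35 genes, 32 were not bright. Among genes kept that were not bright, 17 were called in the same and 15 in opposite directions, against 5.46 and 4.35 for independent lists. Splits of the same 4 arrays that pair p53 or Pontin with the departure gave 23 and 19 shared genes. Simulated unchanged arrays gave 12.1 on average (5 to 20), from fewer calls per knockdown (111 and 110 on average).

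Across genes, the mean p53 ratio and the mean Pontin ratio had a Pearson correlation of 0.0398 and a Spearman correlation of 0.0295 over genes kept, and 0.0383 and 0.0108 over bright genes. Simulated unchanged arrays, in which genes vary independently, gave -0.0333 to 0.0314. The Pearson correlation over genes kept was above that range as deposited but inside it after cyclic loess (0.0213), without a filter on signal (0.00947) and without cross-hybridizing probe set types (0.0306). That range was simulated for the genes kept and was not redrawn for bright genes or alternatives, so places relative to it are approximate there. Genes are not independent replicates, and no p is given. Ratios of the single knockdowns over the shared control array correlated at 0.315, where simulated unchanged arrays gave 0.50. The covariance was 0.0415 against a simulated mean of 0.0441, a difference of -0.0027. It lay inside the simulated range of 0.0411 to 0.0484. However, the simulated noise may be too low for extreme values, and the covariance was 0.106 among genes kept that were not bright. The comparison therefore cannot show or exclude shared or opposed effects. Over bright genes the covariance was 0.0047, not set against a simulation. The correlation there was 0.0954, where simulated unchanged arrays gave 0.498. The simulated arrays carry no knockdown effects, so no direction was read from the lower correlations.

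Signals with both knockdowns were set against the sum of the single log2 effects. TOX3 departed from that sum by -0.25, PIP by 0.15, H2AC6 by -0.26, CCN2 by -0.17 and HDAC8 by -0.02, while RUVBL1 departed by -0.69 and YEATS4 by -0.61. A departure of at least 1.5-fold was seen for 1577 genes kept, 858 upward and 719 downward, but for 201 bright genes. The largest departures belonged to genes of low signal. SPATA32, ANHX, PODNL1, CGAS, ZNF532 and IGDCC3 departed upward, by 4.27 to 3.77, and TMEM38A, CACNG4, UBXN10-AS1, ZNF821, WNT16 and TSGA10IP downward, from -4.17 to -3.16. TMEM38A, for example, had signals of 40.5, 37.5 and 38.8 on the other arrays and 2.0 with both knockdowns. On an equal-noise scale, the departure divided by 2 passed 1.5-fold for 20 bright genes, the mean p53 ratio for 107 and the mean Pontin ratio for 196.

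In cells with both knockdowns compared with the control, TOX3 was at -4.07, RUVBL1 at -2.86, OLFM4 at -2.22, H2AC6 at -1.90 and UBA6 at -1.64, while IGFBP3 was at 1.59, MGP at 1.42 and HDAC8 at 1.33. CCN2 and PSAT1, whose single effects were opposed, were at 0.17 and -0.02. At least 2-fold higher were 308 genes and at least 2-fold lower 176, and among bright genes 36 and 50. The split turned to 202 higher and 285 lower after quantile and 198 higher and 258 lower after cyclic loess normalization. The array with both knockdowns stood apart on its 18 hybridization control probe sets, which averaged 1.42 times those of the control array and were higher on all 18.

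**Figure D3:**
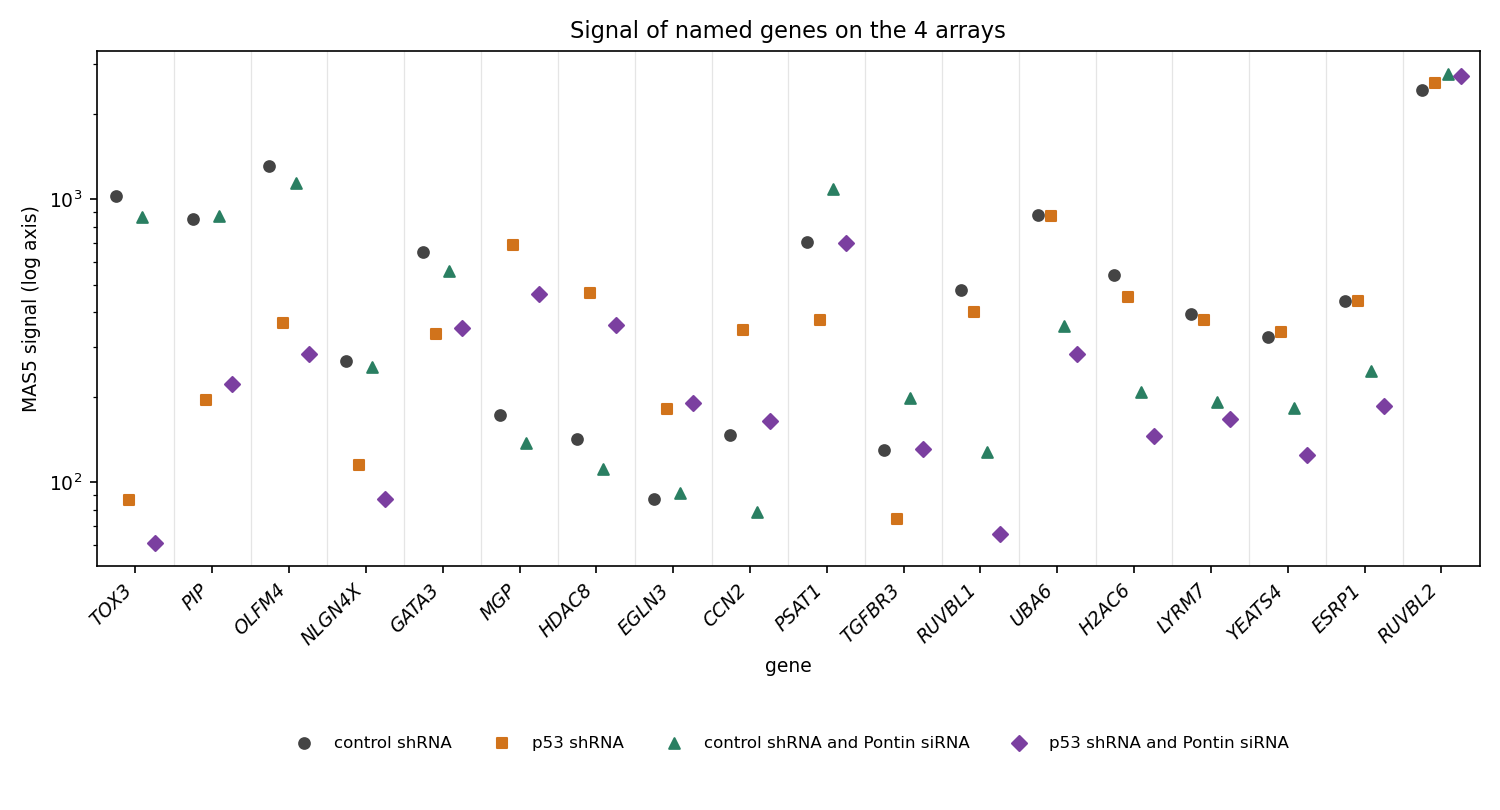
MAS5 signal (log axis) of 18 named genes on the 4 arrays, with 1 marker per array. The p53 shRNA arrays separate from the others for TOX3 (86.3 and 61.2 against 1025.5 and 864.4), the Pontin siRNA arrays for RUVBL1 (127.4 and 65.8 against 477.7 and 398.2), and PSAT1, CCN2 and TGFBR3 show opposite shifts.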

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

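Chosen only after the result was seen were the test of the Pontin pair that leaves out the array with both knockdowns, the test of the G1/S list against culture state, and the test of the RUVBL1 difference between pairs.

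Genes with opposite effects in the 2 pairs of a knockdown, not tested singly, numbered 106 for p53 shRNA and 100 for Pontin siRNA. Array noise and an interaction of the knockdowns were not told apart for these genes. Among the genes with the largest departures from additivity, opposite signs in the 2 pairs of at least 1 knockdown, also not tested, marked SPATA32 (departure 4.27), ANHX (4.10), PODNL1 (4.09), CGAS (3.95), ZNF532 (3.94), IGDCC3 (3.77), CACNG4 (-3.67), UBXN10-AS1 (-3.41), ZNF821 (-3.36), WNT16 (-3.28) and TSGA10IP (-3.16). Outside the gene measurements, hybridization control probe sets on the array with both knockdowns averaged 1.42 times those of the control array.

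Pontin siRNA calls among bright genes were mostly lower, 85 against 14 higher. Scaling between arrays as the whole cause is argued against by the share of lower calls, which was at least 83.2% under median centring, quantile and cyclic loess normalization. The array with both knockdowns is argued against by the pair that leaves it out, where 69.9% of the bright genes at least 1.5-fold apart were lower. An effect of the siRNA on transcripts other than its target, of the transfection, or of the loss of Pontin itself stays open, and these were not told apart.

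The hypoxia and glycolysis list had a median above 0 with p53 shRNA, with 19 of 24 genes above 0 in both pairs. Scaling between arrays is argued against by the list median, which was at least 0.23 under median centring, quantile and cyclic loess normalization. The choice of probe set is not excluded, because the median was 0.05 with the mean over probe sets. That value lay inside the central 95% of random lists, which were not redrawn for that alternative. A difference in growth or culture state between the 2 selected populations cannot be told apart from an effect of the p53 shRNA on its target, because each population may be a single culture that both pairs share, and the G1/S list shifted too, with a median of -0.17.

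Pontin siRNA effects were larger in p53 shRNA cells for 85 of the 99 bright genes called, with a median ratio of the pairs of 1.24. Intensity-dependent differences between arrays are argued against by that ratio, which was at least 1.21 under median centring, quantile and cyclic loess normalization. A wider scale on the array with both knockdowns, as the whole cause, is argued against by p53 effects. Their ratio between the pair with and the pair without that array was 1.01 over the 49 bright genes called in both pairs. Over all bright genes the SD of p53 ratios was 0.224 without and 0.242 with that array. For Pontin ratios it was 0.221 and 0.289, so a smaller widening is not excluded. A deeper Pontin knockdown in that culture cannot be told apart from an interaction with the p53 shRNA, because RUVBL1 itself was lower there by a further log2 difference of -0.69 and each state had 1 array. Either could account for the pattern.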

How the results depend on the processing

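The analyses that left out arrays, and the counts of both knockdowns over control with their alternatives, were chosen after the data were examined. Of 914 values of named genes under alternatives, 794 moved by no more than the SD between the pairs, 120 moved further and 0 changed sign while called. Genes absent under an alternative gave no value there. Of 316 values of gene list medians, 235 moved by no more than the SD between pairs and 81 further. Counts depended on low signal: the noise estimate for a mean ratio, on the log2 scale, went from 0.49 at a median signal of 17 to 0.056 at 4225. The plain SD of the departure divided by 2 was 0.238 over genes kept and 0.117 over bright genes. Without a filter, p53 shRNA gave 1188 genes higher and 719 lower, Pontin siRNA 1186 and 735, both 300 in the same and 243 in opposite directions, 7338 departures, and 2705 genes higher and 1445 lower with both knockdowns over control, with a correlation of the means of 0.00947. Among bright genes these were 17 and 32, 14 and 85, 0 and 3, 201, and 36 and 50. At 2-fold they were 29 and 21, 15 and 14, 2 and 0, and 635 departures. Quantile normalization gave 75 genes higher with Pontin siRNA, and 202 higher and 285 lower with both knockdowns over control; cyclic loess gave 77 and 198 for the first 2 of these and a correlation of 0.0213. The cause was not tested. The pseudocount, which shrinks low-signal ratios, gave 89 genes higher with Pontin siRNA, 7 called for both in the same direction and 116 lower with both knockdowns over control. The limma additive fit, which takes the pairs as replicates and sets no fold threshold, gave 198 genes lower with p53 shRNA, 317 higher and 588 lower with Pontin siRNA, and 33 and 39 called for both in the same and opposite directions at an adjusted p of at most 0.05. With 1 array left out and the rule applied to the remaining pair, p53 shRNA gave 607 to 706 genes higher and 455 to 473 lower, Pontin siRNA 513 to 779 higher and 469 to 643 lower, and both 50 to 438 in the same and 37 to 361 in opposite directions; the remaining pairs then share an array, which by itself adds shared calls. All other counts were within 1.5 times the reported ones.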

Other observations

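Outside the naming rule and chosen after their values were seen, further bright genes were called. With p53 shRNA, the breast-restricted cytochrome P450 gene CYP4Z1 was lower at -1.15 and -1.16 in the 2 pairs, AZGP1, which encodes zinc-alpha-2-glycoprotein, at -0.87 and -1.25, and the adhesion molecule gene CEACAM6 at -0.78 and -1.26. Higher were BASP1, which encodes a membrane-associated signalling protein, at 1.13 and 1.75 (mean 0.79 with the mean over probe sets), and the hypoxia-responsive genes BNIP3L, at 0.63 and 0.68, and ANGPTL4, at 0.64 and 0.79. With Pontin siRNA, the R-spondin receptor gene LGR4 was lower at -0.94 and -1.22 and ZNF267 at -0.96 and -1.21, while SPOPL was higher at 0.78 and 0.98, and CBX1, which encodes heterochromatin protein HP1-beta, at 0.74 and 0.73.

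Several gene lists showed little shift in the mean ratio of both pairs. With p53 shRNA the median was -0.04 for cholesterol synthesis, -0.01 for the proteasome, -0.01 for the unfolded protein and integrated stress response, -0.04 for heat shock, -0.08 for interferon response, 0.03 for NF-kB targets, 0.03 for Pontin and Reptin complexes, -0.05 for PIKK kinases, 0.04 for basal epithelium, 0.08 for mesenchymal genes, 0.02 for immune cells, -0.08 for histones and 0.09 for housekeeping genes, which turned to -0.01 after quantile normalization. With Pontin siRNA it was -0.08 for cholesterol synthesis, 0.03 for the proteasome, 0.01 for the unfolded protein and integrated stress response, 0.07 for heat shock, -0.03 for hypoxia and glycolysis, -0.03 for ribosome biogenesis, 0.04 for mitotic genes, -0.04 for genes reported as raised by mutant p53, -0.10 for basal epithelium, 0.12 for mesenchymal genes and 0.02 for housekeeping genes. The 2 pairs of the mesenchymal list disagreed. Its Pontin siRNA medians were 0.12 in control shRNA cells and -0.27 in p53 shRNA cells. Its p53 shRNA medians were 0.29 without and -0.01 with Pontin siRNA. In the same order, p53 shRNA medians also differed in sign for interferon response (0.09 and -0.14) and basal epithelium (-0.06 and 0.16). Some lists with medians nearer 0 did so as well. Immune cell genes, of which 4 of 17 were kept and 0 were bright, had a median near 0 with Pontin siRNA. ACTA2, a smooth muscle actin gene of the mesenchymal list, was called higher with p53 shRNA by 2.04-fold and 2.01-fold from signals of 19.8 and 14.9. Signs of medians within 0.10 of 0 turned under some alternatives for the p53 lists of cholesterol synthesis, proteasome, stress response, interferon, NF-kB, PIKK and immune cells, and for the Pontin lists of cholesterol synthesis, stress response, hypoxia, ribosome biogenesis, mutant p53 genes, immune cells and housekeeping genes.

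Among 4513 probe sets above the signal filter with several symbols or none, p53 shRNA gave 125 higher, 49 lower and 154 opposite in sign, and Pontin siRNA 142 higher, 52 lower and 119 opposite. Signal ratios of the 3' over the 5' ACTB control probe sets were 3.21 with control shRNA, 3.48 with p53 shRNA, 2.66 with Pontin siRNA and 2.96 with both, and those of GAPDH lay between 0.97 and 1.04.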
